A study of Mus musculus with 6 samples.

How the data were processed

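RNA-seq data came from 6 libraries of cells labelled as primary mouse renal fibroblasts, all given TGF-β at 5 ng/ml for 48 h. In 3 libraries the cells had received a scrambled control siRNA, and in 3 they had received siRNA against Prune2. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 3 replicates of a group were separate isolations, separate cultures or repeat libraries, so p-values measure the spread between these libraries, which may be technical. Replicate libraries were compared by chi-square over genes with at least 10 summed counts. Each pair within a group gave between 2.57 and 3.92 per degree of freedom, above sampling noise, so no library was treated as a second copy of another. The comparison cannot tell repeat libraries of the same culture from separate cultures or isolations.

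The authors deposited 1 table of 22274 genes that holds, per the file headers, a read count and an FPKM value (fragments scaled to transcript length and library size) for each library. It also holds the authors' mean FPKM of each group, a log2 fold change, a p-value and an adjusted p-value for Prune2 siRNA over control siRNA, and pathway annotation. The deposited log2 value equals the log2 ratio of the mean FPKM columns to within 2e-14. Genome builds GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the counting tool, the treatment of reads shared between gene copies and the test behind the authors' deposited p-value columns are not given in the sources used here. The gene length implied by the ratio of the deposited count to the deposited FPKM is not fixed: among 2213 genes with over 2000 counts in every library, 24.4% had implied lengths that differed by over 5 percent between libraries. A fold change in FPKM can therefore differ from the fold change in counts.

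Gene identifiers were matched to the GENCODE M21 annotation of GRCm38 for symbols and positions, and 22219 of the 22274 were found there, leaving 55 without a match. Library totals ran from 20075265 to 23234797 counts. Of the genes in the table, 17028 had a count in at least 1 library and 5246 had 0 in all 6.

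Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over the 13248 genes that passed the filter. A gene is called changed at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM, counts divided by the TMM-scaled library sizes and brought to edgeR's common scale. Sums over marker lists and marker levels in the closing section use TMM factors and library sizes over all genes in the table, so that untested members have a value. Single values were compared with an exact two-sided permutation test, for which 3 libraries against 3 cannot give a p under 0.1.

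Before the data were examined, 26 gene lists were fixed. They cover matrix, contractile, TGF-β, YAP, mesenchymal, cell cycle, interferon, inflammatory, p53, BCL2 family, stress, hypoxia, cholesterol, respiratory chain and lysosome genes, ribosomal, histone and mitochondrially encoded transcripts, and markers of fibroblasts, pericytes, tubular epithelium, endothelium, leukocytes and podocytes. Of 830 listed symbols, 4 (Rigi, Ddit3, Aldoa and Atp5o) were not matched by symbol, which does not mean that the genes are absent from the table. The ribosomal, histone and mitochondrially encoded lists were taken from the table by symbol, so their members could not go unmatched. Each list was compared with the other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 26 lists, and again with a correlation estimated from the data. Fry was run as a further test. Pathways came from the annotation in the deposited table and were tested with camera where they held 10 to 300 tested genes. Genes named in the text are Prune2, genes set in advance (Acta2, Col1a1, Col3a1, Fn1, Ccn2, Tagln and Postn), and the 10 largest rises and 10 largest falls. The last 2 sets required a call, at least 1 CPM in the higher group, separated groups and a gene symbol that is not an identifier. In each list described, up to 2 called members per direction with the smallest adjusted p are named too, and others only to resolve small counts. Some genes that this rule names are not reported here.

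The procedure was tested on simulated counts drawn from the means and library sizes of these libraries over 13152 genes. Of genes changed 1.2-fold, 48% were recovered, against 77.6% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and 9 of 165 calls were false. Camera found the simulated list of 40 genes moved 1.2-fold and called 0 of 20 unmoved lists. Simulated genes were drawn independently of each other. The simulation therefore does not test camera on lists with correlated members, such as the interferon list (estimated correlation 0.433).

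Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) with genes at 1 FPKM or more in at least 3 libraries, a pseudocount of 0.1, no FPKM filter, the replicate number as a block, a 2-fold minimum and leaving out each library in turn. Trends on GC content and transcript length were fitted with mgcv 1.9.3. Figures were drawn with matplotlib 3.10.9.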

Results

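The libraries measured transcript levels in cultured mouse cells labelled as primary renal fibroblasts, all treated with TGF-β, a cytokine that turns fibroblasts into contractile, matrix-producing myofibroblasts. The comparison asked which genes respond when Prune2 is depleted in these TGF-β-treated cells. There were 3 libraries with control siRNA and 3 with Prune2 siRNA. Total counts were 20608177, 20075265 and 23035593 in control replicates 1, 2 and 3, and 21126240, 22969089 and 23234797 in Prune2 siRNA replicates 1, 2 and 3. Libraries without TGF-β were not analysed here, so no value below measures the response to TGF-β itself. Unless another test is named, adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and log2 fold changes are Prune2 siRNA over control siRNA.

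Prune2 was lower in each of the 3 Prune2 siRNA libraries than in any control library, and the depletion was partial. Its mean level was 6.95 ± 0.775 CPM (SD, n = 3) in control libraries and 3.80 ± 0.629 CPM (SD, n = 3) with Prune2 siRNA, a fall of 45.2%. Prune2 (ENSMUSG00000039126) is a protein-coding gene on chromosome 19, from 16956118 to 17223932 on the plus strand of GRCm38. Its counts were 133, 157 and 150 in the control libraries and 80, 73 and 104 in the Prune2 siRNA libraries. The log2 fold change of Prune2 was -0.87 (SE 0.15, adjusted p = 0.000214), and the exact two-sided permutation test of the 6 CPM values gave p = 0.1, the smallest it can give. The size of the fall differs by unit: mean FPKM of Prune2 in the deposited values fell by 28.2%, since the gene length implied by count and FPKM averaged 5873 ± 159 bases in control libraries and 4491 ± 537 bases with Prune2 siRNA (SD, n = 3). On log2(FPKM + 1), limma gave an adjusted p of 0.218 for Prune2.

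**Figure D1:**
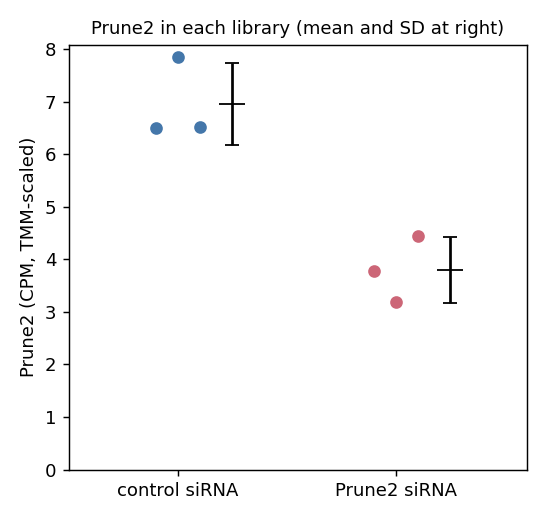
Prune2 level (CPM) in each library, by siRNA group. Points are libraries, the line and bar at the right of each group are the mean and SD, and the 3 Prune2 siRNA libraries (3.19 to 4.44 CPM) lie below the 3 control libraries (6.50 to 7.85 CPM).

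With Prune2 siRNA, leukocyte markers had the lowest median log2 fold change of the 26 gene lists (-2.64) and interferon response genes the highest (0.99). The medians of the matrix, contractile and TGF-β pathway lists were -0.23, -0.09 and -0.08. Of 13248 tested genes, 1364 changed (10.3%), with 591 higher and 773 lower, and the median fold among them was 1.26. At least a 2-fold difference was seen for 52 of the higher and 243 of the lower genes. The 10 largest falls passing the naming rule were Evi2b, Tmem273, Parvg, Cx3cr1, Pf4, Ms4a6b, Pld4, Pilra, Ppfia4 and Trem1. Cx3cr1, the fractalkine receptor of monocytes and macrophages, went from 4.42 ± 1.77 to 0.233 ± 0.168 CPM (SD, n = 3; log2 fold change -4.19, SE 0.38, adjusted p = 1.08e-08). Evi2b (chromosome 11, 79515056 to 79523762), a membrane protein of blood cells, had the lowest log2 fold change of the named genes at -5.05 (SE 0.47), with 166 summed control counts against 5. Without Prune2 siRNA replicate 3, the log2 fold change was -4.96 for Cx3cr1 and -5.69 for Evi2b. In that fit Parvg, at 0 CPM in Prune2 siRNA replicates 1 and 2, went from -4.2 to -7.68, below Evi2b. Tmem273 had 65 summed control counts against 3, a ratio of 22.9 with an exact 95% counting interval of 7.5 to 114, and its fitted log2 fold change went from -4.36 to -5.24 without Prune2 siRNA replicate 1. The 10 largest rises passing the rule were Ifit1, Apol9a, Rtp4, Iigp1, Tgtp2, Rsad2, Xaf1, Isg15, Irf7 and Ifit1bl1. Ifit1 (chromosome 19, 34640871 to 34650009), an interferon-induced antiviral protein, rose from 1.33 ± 0.868 to 9.95 ± 3.32 CPM (SD, n = 3; log2 fold change 2.91, SE 0.27, adjusted p = 1.31e-08), and its log2 fold change was 3.53 without control replicate 2. Ifit1 and Ifit1bl1, Apol9a and Tgtp2 have near-identical copies in the genome, so their separate values are uncertain.

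The groups did not overlap for 3214 of the 13248 tested genes (24.3%), where chance gives 10% for 3 libraries against 3. The authors' deposited table gives an adjusted p under 0.05 for 1033 genes, with 421 higher and 612 lower, and 1007 of them were also called here. Pak3 alone had opposite signs, with a log2 fold change of 0.24 by counts and -0.08 in the authors' deposited table. Limma on log2(FPKM + 1), which changes the unit, the test and the filter together, called 620 genes.

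**Figure D2:**
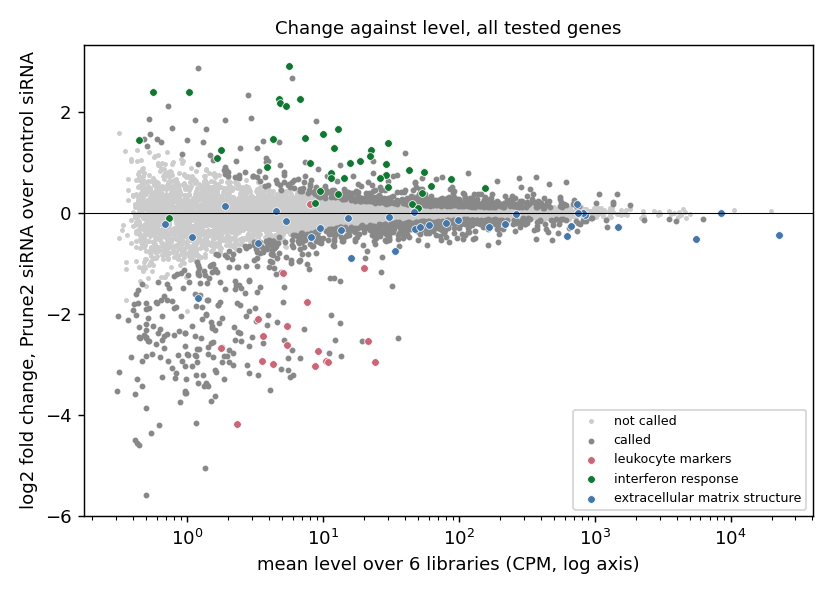
Log2 fold change (Prune2 siRNA over control siRNA) against mean CPM over the 6 libraries on a log axis, for the 13248 tested genes. Light grey points were not called and dark grey points were, and coloured points are members of 3 lists: leukocyte markers lie mostly below 0 (median -2.64), interferon response genes mostly above 0 (median 0.99) and matrix genes slightly below 0 (median -0.23).

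Leukocyte markers were almost all lower, but by differing amounts. The log2 fold changes of the called members ran from -1.09 (Csf1r, SE 0.08) to -4.19 (Cx3cr1, SE 0.38). Of 18 tested markers 17 fell and 0 rose, both over all genes and adjusted over the list alone, with a median log2 fold change of -2.64 (camera adjusted p = 3.8e-138, and adjusted p = 0.0186 with an estimated correlation). Cd74, the invariant chain of MHC class II, went from 42.7 ± 2.30 to 5.50 ± 0.680 CPM (SD, n = 3; log2 fold change -2.95, SE 0.09, adjusted p = 7.37e-18). Laptm5, a lysosomal membrane protein of blood cells, went from 15.9 ± 0.897 to 2.38 ± 0.180 CPM (SD, n = 3; log2 fold change -2.74, SE 0.12). Cd14, the lipopolysaccharide co-receptor, was the member not called (log2 fold change 0.18, SE 0.12, adjusted p = 0.459). Summed over the list, markers stood at 262, 275 and 224 CPM in the control libraries and 56.1, 56.3 and 59.3 CPM in the Prune2 siRNA libraries.

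Interferon response genes rose while the leukocyte markers fell. Of 41 tested genes 37 rose and 0 fell, or 38 and 0 adjusted over the list alone, with a median log2 fold change of 0.99 (camera adjusted p = 4.54e-71, and adjusted p = 0.0418 with an estimated correlation). Ifit3 rose 2.63-fold, from 16.5 ± 3.63 to 43.5 ± 2.19 CPM (SD, n = 3; adjusted p = 5.57e-11), although it shares sequence with Ifit3b. Ifi27 rose 2.38-fold (adjusted p = 2.03e-11). Isg15, a ubiquitin-like modifier, rose 4.52-fold, and Irf7, a transcription factor that amplifies interferon production, rose 4.33-fold. Xaf1, Rsad2 and Iigp1 rose 4.76-fold, 4.76-fold and 5.27-fold, and Xaf1 7.73-fold without control replicate 2.

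Matrix, crosslinking and contractile genes were modestly lower, in the same libraries in which 17 of 18 leukocyte markers and 7 of 16 endothelial markers were lower. Of 33 tested structural matrix genes, 16 fell and 1 rose, or 19 and 1 adjusted over the list alone (median log2 fold change -0.23, camera adjusted p = 2.47e-14, and adjusted p = 0.0418 with an estimated correlation). Fn1, which encodes fibronectin, fell from 26290 ± 320 to 19430 ± 1085 CPM (SD, n = 3; log2 fold change -0.44, SE 0.04, adjusted p = 2.1e-08). Tnc (tenascin C) fell by 0.52 on the log2 scale and Sparc by 0.44. Col18a1 was the member that rose (log2 fold change 0.18). Col1a1, the type I collagen chain, fell by 0.21 (SE 0.04, adjusted p = 0.000682), while Col3a1, the type III chain, stood at 15.7 ± 2.14 and 14.7 ± 1.73 CPM (SD, n = 3; adjusted p = 0.697). Postn (periostin) fell by 0.33 (adjusted p = 0.0166), but its adjusted p was 0.114 without control replicate 1, 0.0683 without Prune2 siRNA replicate 1 and 0.0663 without Prune2 siRNA replicate 3 (0.00616 to 0.114 over 17 alternatives). Of 24 crosslinking and collagen-processing genes 8 fell and 1 rose, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.8e-05, and adjusted p = 0.0418 with an estimated correlation), with Loxl2, a collagen crosslinking oxidase, at -0.38 and Plod2, a collagen lysyl hydroxylase, at -0.36.

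Contractile genes were also lower as a list, again beside the lower leukocyte markers (median -2.64). Of 35 tested, 13 fell and 1 rose, or 14 and 3 adjusted over the list alone (median log2 fold change -0.09, camera adjusted p = 1.01e-05, and adjusted p = 0.0418 with an estimated correlation). Acta2, the α-smooth muscle actin that marks myofibroblasts, fell from 715 ± 23.4 to 586 ± 30.8 CPM (SD, n = 3; log2 fold change -0.29, SE 0.04, adjusted p = 7.31e-06). Tagln, an actin-binding protein, fell by 0.39 and the fibronectin receptor chain Itga5 by 0.31. Of 18 mesenchymal transcription factor and EMT genes 5 fell and 0 rose, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.000182, and adjusted p = 0.0418 with an estimated correlation), led by Vim at -0.53 and Cdh11 at -0.32.

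Among TGF-β pathway genes Tgfbi fell further than any other tested member, and leukocyte markers (median -2.64) were lower in the same libraries. Of 40 tested, 11 fell and 1 rose, or 16 and 2 adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 2.98e-06, and adjusted p = 0.0418 with an estimated correlation). Tgfbi, a secreted matrix protein also made by macrophages, fell 5.69-fold (log2 fold change -2.51, SE 0.12, adjusted p = 6.92e-14), Inhba, an activin subunit, fell 1.42-fold, and Tgfbr2, a TGF-β receptor, rose 1.15-fold. Ccn2, a matricellular TGF-β target, had a log2 fold change of -0.10 and missed the threshold (adjusted p = 0.0611). It passed in 6 of 17 alternatives, DESeq2 and limma-voom among them, with adjusted p from 0.0036 to 0.302 over the 17, and 0.0496 without Prune2 siRNA replicate 1. Of 24 matrix proteases and inhibitors 8 fell and 4 rose, or 10 and 5 adjusted over the list alone (camera adjusted p = 1.35e-08, and adjusted p = 0.0418 with an estimated correlation). Mmp12, the macrophage elastase, fell 5.52-fold and Mmp13, a collagenase, 4.51-fold, while Adamts5, an aggrecanase, rose 1.3-fold and Timp3, a protease inhibitor, 1.17-fold. Without the members that changed by at least 2-fold, an alternative chosen after the data were seen, the protease list gave a camera adjusted p of 0.0823.

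Inflammatory genes moved in both directions, in libraries where leukocyte markers were lower (median -2.64). Of 33 tested, 9 rose and 3 fell, or 11 and 3 adjusted over the list alone. Their median log2 fold change was 0.08 and their mean -0.03, and the list was called upward by camera (adjusted p = 0.00969) but not with an estimated correlation (adjusted p = 0.407 with an estimated correlation). Il1b and Il1a, the interleukin-1 cytokines that leukocytes release, fell 11.3-fold and 9.2-fold, and Cxcl12 also fell. Lcn2 (lipocalin-2), which injured tubular epithelium secretes, rose from 488 ± 19.1 to 748 ± 2.58 CPM (SD, n = 3; adjusted p = 3.49e-12), and complement C3 rose 2.28-fold.

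Most cholesterol synthesis genes rose by a small amount, in libraries where 17 of 18 leukocyte and 7 of 16 endothelial markers were lower, as they were beside the ribosomal, cell cycle and histone genes that follow. Of 26 tested, 19 rose, 0 fell and 7 were not called, or 21 and 1 adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 1.1e-12, and adjusted p = 0.167 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, rose 1.22-fold. Of 82 ribosomal protein genes, matched by symbol, 8 rose and 0 fell, or 9 and 0 adjusted over the list alone (median log2 fold change 0.07, camera adjusted p = 2.2e-07, and adjusted p = 0.407 with an estimated correlation), with Rps12 and Rps16 rising 1.13-fold and 1.15-fold. Of 40 cell cycle genes, Mki67, Top2a and Bub1b fell and 0 rose, with 2 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.00315, and adjusted p = 0.167 with an estimated correlation). Top2a lost its call without control replicate 2 (adjusted p = 0.0546), control replicate 3 (0.105), Prune2 siRNA replicate 1 (0.0552) or Prune2 siRNA replicate 2 (0.0841), with 0.0139 to 0.211 over 17 alternatives. Of 20 histone genes 4 fell and 0 rose, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.167 with an estimated correlation), and the list lost its call without control replicate 2 (0.0872), Prune2 siRNA replicate 1 (0.0689) or Prune2 siRNA replicate 3 (0.0553), and with upper-quartile scaling (0.0572).

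**Figure D3:**
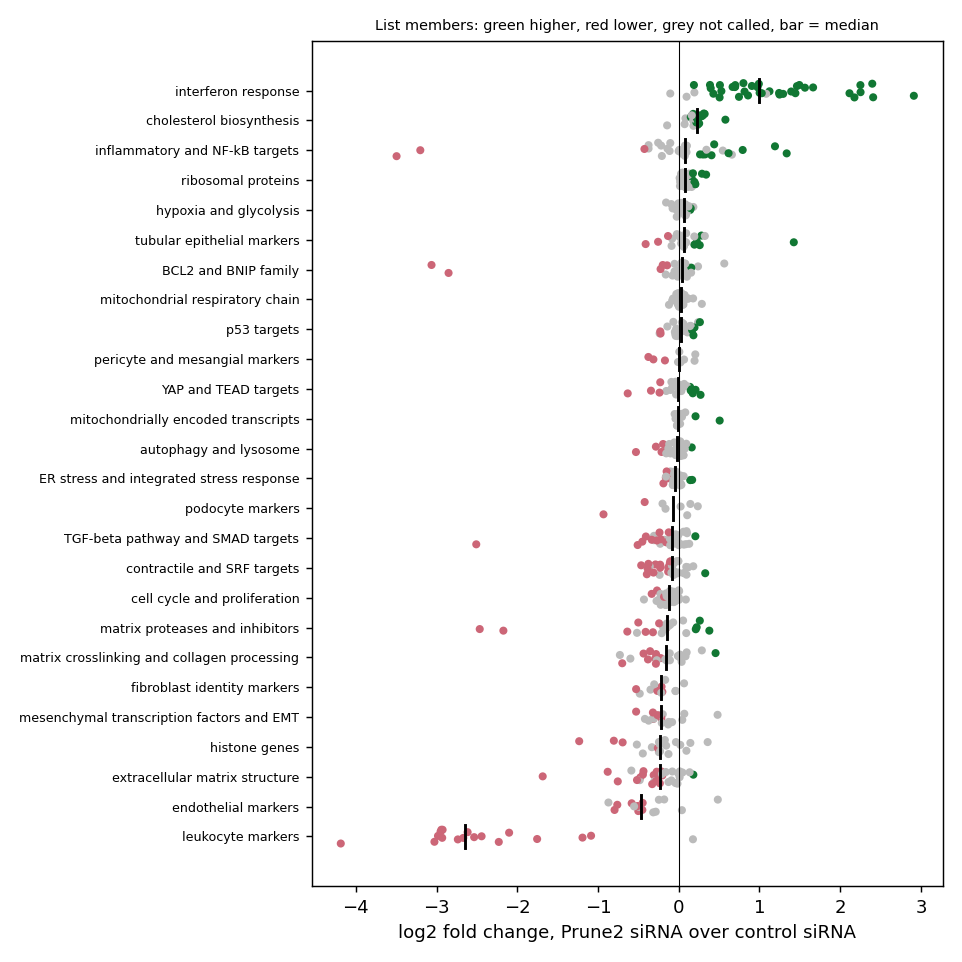
Log2 fold change (Prune2 siRNA over control siRNA) of each tested member of the 26 lists, with list medians as black bars. Green points were called higher, red points lower and grey points neither, and the lists run from leukocyte markers (median -2.64) to interferon response genes (median 0.99).

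Markers of other kidney cell types did not move alike. Of 12 tested fibroblast identity markers 4 fell and 0 rose, or 5 and 0 adjusted over the list alone (median log2 fold change -0.22, camera adjusted p = 0.00129, and adjusted p = 0.0713 with an estimated correlation). The 4 were Vim, Col1a1, Col1a2 and Lsp1. Of 16 endothelial markers 7 fell and 0 rose, with the same counts adjusted over the list alone (median -0.47, camera adjusted p = 6.77e-07, and adjusted p = 0.0713 with an estimated correlation), and Cdh5, the endothelial cadherin, fell 1.42-fold and Emcn 1.36-fold. Of 21 tubular epithelial markers 5 rose and 3 fell, both over all genes and adjusted over the list alone (median 0.06, camera adjusted p = 0.0583). Slc12a3, the distal tubule sodium chloride cotransporter, rose from 1.99 ± 0.270 to 5.32 ± 1.26 CPM (SD, n = 3), and Cdh16, the kidney cadherin, rose 1.22-fold, while Lrp2, the proximal tubule receptor megalin, fell 1.19-fold. The tubular list passed the threshold without control replicate 3 (adjusted p = 0.0461) and without Prune2 siRNA replicate 2 (0.0105), with 0.0105 to 0.315 over 13 alternatives. Of 9 pericyte markers 3 fell, or 3 with 2 rising adjusted over the list alone (camera adjusted p = 0.232). Of 8 podocyte markers 2 fell, with 2 also adjusted over the list alone (0.35).

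**Figure D4:**
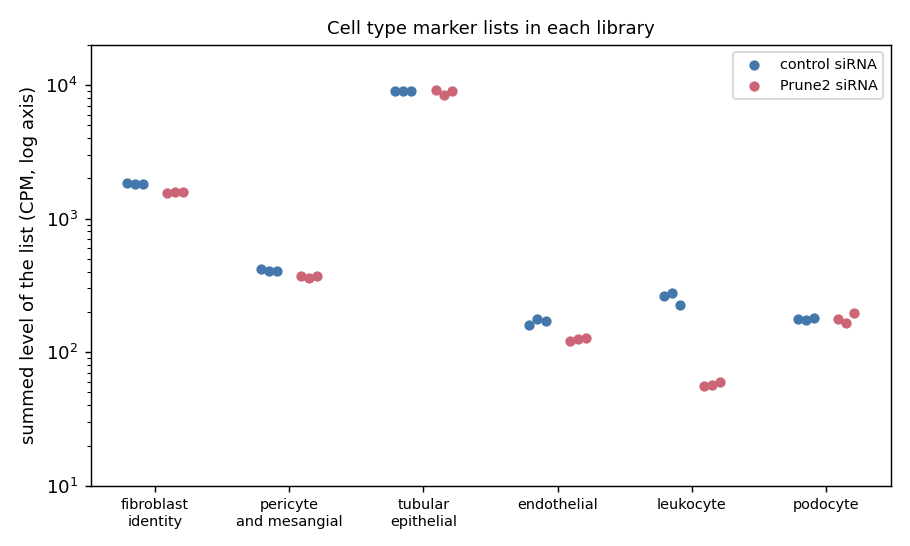
Summed CPM of 6 cell type marker lists in each library, on a log axis. Points are libraries; leukocyte markers sum to 224 to 275 CPM in control and 56.1 to 59.3 CPM in Prune2 siRNA libraries, and tubular epithelial markers sum to 8396 to 9105 CPM over the 6 libraries.

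The remaining lists were not called by camera. The counts higher and lower were 6 and 4 of 22 YAP and TEAD targets (adjusted over the list alone 7 and 5; camera adjusted p = 0.735), with Wwc1 at 0.27 and Nt5e, an ectonucleotidase, at -0.63. They were 5 and 2 of 27 p53 targets (7 and 3; 0.246) and 1 and 5 of 29 BCL2 and BNIP family genes (1 and 5; 0.735), among which Bcl2a1b, a survival gene of blood cells with near-identical copies, had the lowest value at -3.06. For endoplasmic reticulum stress they were 2 and 4 of 33 genes (2 and 5; 0.136), and the list passed without control replicate 3 (0.00571) or Prune2 siRNA replicate 1 (0.0218). For hypoxia and glycolysis they were 2 and 0 of 28 (1 and 0; 0.0583), and the list passed without control replicate 2 (0.0158), Prune2 siRNA replicate 2 (0.0143) or Prune2 siRNA replicate 3 (0.0402). For autophagy and lysosome genes they were 1 and 5 of 34 (1 and 5; 0.177), with Ctsz, a cathepsin, at -0.53. The respiratory chain had 0 and 0 of 37 (0 and 0; 0.194), passing without Prune2 siRNA replicate 2 (0.033), and mitochondrially encoded transcripts had 2 and 0 of 13 (2 and 0; 0.336), passing without control replicate 1 (0.0412).

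Among pathways from the deposited annotation, those with the smallest adjusted p were immune ones and were lower with Prune2 siRNA, in the same libraries in which 17 of 18 leukocyte markers were lower. Of 317 tested, 48 were called by camera, with 40 lower and 8 higher. Staphylococcus aureus infection had the smallest adjusted p (3.76e-35), with 21 genes lower and 3 higher of 38, followed by asthma, leishmaniasis and rheumatoid arthritis, all lower. For these 4 the call was lost (adjusted p = 0.0956, 0.0858, 0.147 and 0.152 with an estimated correlation). Ribosome, steroid biosynthesis (10 of 17 genes higher, adjusted p = 0.000289) and RIG-I-like receptor signalling (7 of 48 genes higher) were among the 8 called higher, with adjusted p = 0.714, 0.29 and 0.393 with an estimated correlation. With an estimated correlation camera called 0 pathways, with 54 at an unadjusted p under 0.05 and the smallest adjusted p = 0.0858 with an estimated correlation.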

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

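The tests of leukocyte number and of leukocyte genes outside antigen presentation and complement were chosen only after the result was seen, as was the reading of the tubular marker bound. The study's own biological difference, depletion of Prune2, stays open and untested for each of the 3 patterns, because each group has a single siRNA label.

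Leukocyte markers were lower with Prune2 siRNA, by a median of -2.64 on the log2 scale. The values argue against normalization or depth, since the highest list median over 3 other scalings was -2.63. The fall was not confined to antigen presentation and complement genes: the median of 5 pan-leukocyte genes (Ptprc, Laptm5, Coro1a, Tyrobp and Fcer1g) was -2.67. These 5 are members of the same list and were chosen after their values were seen. Their median describes the pattern and is no independent test of it. Fewer leukocytes in the Prune2 siRNA cultures stays open as a candidate explanation: 94.4% of the tested members were called lower, which restates the pattern and does not test it. The called members fell by differing amounts, from -1.09 (Csf1r) to -4.19 (Cx3cr1). Whether a change of number alone would give such a range was not tested. The most abundant member, Cd74, was at 42.7 CPM in control libraries, and the labels name no sort that would remove leukocytes. Whether a smaller number would come from Prune2 depletion, from the siRNA itself or from differences between isolations stays open.

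Interferon response genes were higher with Prune2 siRNA, by a median of 0.99 on the log2 scale. Loss of leukocyte RNA from the total would move them no more than all genes. Their median exceeded that of all tested genes by 0.988, but TMM scaling holds the latter near 0 (0.004), so this nearly restates the pattern. With library totals in place of TMM, the median of all tested genes was 0.013. A shift of that size is far below 0.99 and argues against this explanation. GC content and length bias also fails to account for the rise, as 99.3% of the median was kept after that trend was removed. Innate sensing that differs between the siRNA duplexes and an effect of Prune2 depletion cannot be told apart, because the number of siRNA labels per group was 1.

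Matrix transcripts were lower, by a median of -0.23 on the log2 scale. GC content and length bias is argued against, since 99.4% of the difference between the tubular epithelial and matrix medians was kept after that trend was removed. A smaller share of fibroblasts in the culture stays open: the fibroblast identity list had a median of -0.215, close to that of the matrix list. Its 8 tested members outside the matrix list had a median of -0.241, with 2 of them called, Vim and Lsp1. The others were not called and ran from Cd34 (-0.35, SE 0.129) to Pdgfrb (0.066, SE 0.093), with Pdgfra at -0.039 (SE 0.157). Few of these 8 members were called, and they were not tested as a set of their own. The whole list of 12 tested members, which shares genes with the matrix list, was lower by camera (adjusted p = 0.00129) and by fry (adjusted p = 0.00609). Camera with an estimated correlation did not call it (adjusted p = 0.0713), so a fall as a set depends on the test. A larger share of tubular epithelial cells stays open too, with 62.5% of the called tubular members higher (5 of 8). The bound set beforehand, at least 3 members higher and 3 lower, was met and would have excluded this, but that bound was wrong for abundant markers: the tested tubular list summed to between 8395 and 9105 CPM, against 1562 to 1840 CPM for the fibroblast list, so a small shift in share would hardly move it.

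The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1364 genes in edgeR and was the 1 split with as many. The highest of the others gave 0, with 246 to 660 genes at an unadjusted p under 0.05. Every other split has libraries of both siRNA groups on each side, so the group difference enters its residual spread and lowers its calls. The 0 therefore does not show what libraries without a group difference would give.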

How the results depend on the processing

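Leaving out members that changed by at least 2-fold was chosen after the data were seen. Under the 3 other scalings, both filters, DESeq2 and limma-voom, the count of changed genes stayed between 1071 and 1605 (1364 as reported), and Prune2 stayed called. Limma on FPKM, which changes the unit, the test and the filter together, moved the counts: log2(FPKM + 1) called 620 genes (313 higher, 307 lower), a pseudocount of 0.1 gave 610 (309 and 301), and no FPKM filter gave 593 (221 and 372). The differences of log2(FPKM + pseudocount) for Prune2 were -0.238, -0.432 and -0.238, with adjusted p of 0.218, 0.216 and 0.134. The pseudocount shrinks such differences at a level near 1 FPKM (the authors' deposited table gives -0.479), and FPKM divides by the implied gene length. The cause of the lower counts was not tested. Requiring at least 2-fold left 295 genes (52 higher, 243 lower). With an estimated correlation 8 lists were called in place of 15, and 0 pathways in place of 48. The fibroblast and histone lists lost their calls at estimated correlations of 0.009 and -0.013, under the preset 0.01. A higher correlation therefore does not explain every loss, and the cause was not tested. Fry called 13 lists. Without members past 2-fold, 12 lists were called, and the leukocyte list kept 1 gene, Cd14, at 0.176, by construction. Leaving out each library gave 997 to 1249 changed genes (401 to 551 higher, 596 to 708 lower), Prune2 between -0.999 and -0.751, and 15 to 18 lists, with fewer libraries in each fit. Among named genes other than Prune2, DESeq2 ended 10 calls and added 1, log2(FPKM + 1) ended 18, and leaving out a library ended between 3 and 15. With the replicate number as a block, 1490 genes were called (664 higher, 826 lower), with 52 pathways and 16 lists, the added list being tubular epithelial markers (adjusted p = 0.0452). Same-numbered libraries correlated at 0.13, 0.009 and 0.054 in their deviations from the group means, against -0.187 to 0.131 for differently numbered ones. Not every library correlated best with its own number. With so few libraries these values neither show nor exclude pairing, and the labels state none. At 20075265 to 23234797 counts per library, simulated 1.2-fold changes were recovered in 48% of genes, so small changes can be missed. The simulation held fewer changed genes (165 calls against 1364), which lowers recovery at an adjusted threshold. Depth was not varied, so the loss cannot be put down to depth.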

Other observations

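The labels describe renal fibroblasts, and the fixed list of tubular epithelial markers stood above the fixed list of fibroblast identity markers in each of the 6 libraries. The median member was at 94.7 to 110 CPM for the 26 tubular markers and at 0.74 to 1.35 CPM for the 20 fibroblast markers, and 16 to 18 tubular against 6 fibroblast members reached 10 CPM. Single genes of the lists overlapped in level. The genes named here were chosen after their values were seen. Krt8, a keratin of simple epithelia, averaged 2310 CPM over the 6 libraries (2060 to 2460), Cldn4, a tight junction protein, 1480 CPM (1390 to 1530), Cdh1, the epithelial cadherin, 1030 CPM (958 to 1080) and Epcam 429 CPM (413 to 448). Cdh16, the kidney cadherin, averaged 346 CPM and Pax8, a transcription factor of the renal epithelium, 104 CPM, while Umod was at 1.38 CPM in control and 1.58 CPM in Prune2 siRNA libraries and Hnf4a at 1.28 and 1.61 CPM. Among fibroblast genes, Fbln2 was at 862 CPM in control and 838 CPM in Prune2 siRNA libraries, above Epcam, Cdh16 and Pax8. Col1a1 averaged 220 CPM (191 to 239), Pdgfrb 20.2 CPM, Col3a1 15.2 CPM, Pdgfra 4.94 CPM and Thy1 0.547 CPM, and Dcn, which encodes decorin, had 50 counts over the 6 libraries together. Acta2 averaged 650 CPM and Vim 482 CPM, and both are also expressed outside fibroblasts. The proportion of each cell type was not estimated.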
